A study of Mus musculus with 24 samples.

How the data were processed

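Bulk RNA-seq was measured in mouse alveolar macrophages lavaged from the lungs at 5 postnatal ages from 1 to 49 days (D1, D3, D7, D21 and D49) and kept for 4 h with 400 ng/mL LPS or in medium without LPS, per the labels. Each library holds macrophages pooled from several mice, per the labels. The 24 libraries form 10 groups of 2 or 3 libraries, 13 of control cells and 11 of LPS-treated cells. The labels do not state that replicates of a group come from separate animals, so the p-values measure spread between these samples, which may be technical.

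RNA was isolated with a column kit for small samples, messenger RNA was selected with oligo-dT beads and libraries were made with a commercial kit, per the sample records. STAR, DESeq2 and the mouse build GRCm39 are named in the submitters' processing notes; their versions, the counting tool and the gene annotation are not given in the sources used here. The deposited table gives whole-number counts (unit: count) per Ensembl gene, with exonic lengths beside them, although its name mentions FPKM. The design, written before the data were examined, had assumed FPKM and named edgeR for the case that counts were found, and that case was followed.

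The table has 56691 genes; 52073 were given a symbol from GENCODE M21, a GRCm38 annotation, so no coordinates are printed. Genes without a symbol held 0.904% of counts and 324 of the tested genes. FPKM was computed from the counts, the exonic lengths and the library totals. Genes with FPKM of at least 1 in 2 or more libraries were tested, 11774 in all. Counts were fitted with the quasi-likelihood (QL) test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and a separate mean for each of the 10 groups. Adjusted p-values are those of edgeR QL after Benjamini-Hochberg correction over all tested genes, and a gene passed at an adjusted p under 0.05. Each log2 fold change is given with its standard error, derived from the QL F statistic. Group levels are mean TMM-scaled CPM (a library's counts scaled to a common total) ± SD. The order of comparison is LPS minus control and later minus earlier age; the difference in LPS response is the D49 response minus the D1 response.

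Lists of genes were written down before the data were examined: 19 pathway lists and 12 lists of markers of other cell types. Lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg correction over the 22 lists tested; the test was repeated with the correlation estimated from the data. The marker lists tested were neutrophil, lung epithelial and monocyte; in the others too few genes were tested: eosinophil 2, mast cell and basophil 0, T and NK cell 2, B cell 0, dendritic 4, endothelial 3, fibroblast 1, erythroid 4 and platelet 1. For each list the genes passing among all tested genes are given, with the number passing after correction over the list alone.

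Genes named were set by a rule fixed before the data were examined. For the LPS responses at D1 and D49, the control difference from D1 to D49 and the difference between those LPS responses, the 6 largest rises and the 6 largest falls were named among genes that passed and had a mean FPKM of at least 5 in the higher group. For other comparisons the 3 largest rises and falls were named. Predicted genes with Gm or Rik names were left out of that rule. Tnf, Il1b, Il6, Il10, Cxcl10, Ifnb1, Tlr4, Cd14, Marco, Mrc1, Fcgr1, Siglecf, Pparg and Mki67 were always reported, and 2 to 4 members that passed were named for lists described, not always those with the largest change. Oas3, Mmp19, H2-T24, Samhd1, Car6, Smgc, Fgb, Mbl1, Tdo2, Slco1b2, Ugt2b35 and Zcchc24 were chosen after the values were seen. A few genes that the rule or this choice named are not reported here.

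Library totals were 15.8 to 23.3 M counts. Spearman correlation across genes between replicates was 0.922 to 0.992, and no pair of replicates was a copy, the smallest chi-square per degree of freedom being 13.7. A bound of 3 counts per library was used where a group had no count, which gave group means of 0.128 to 0.186 TMM-scaled CPM. Such folds are printed as at-least folds and cover counting error only. Groups with 1 to 3 counts are given as CPM. The table held 0 further per-sample columns and 0 lines without a gene identifier.

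GC deviation was defined for each library as the median log2 deviation from the mean over libraries in the 10% of tested genes with the highest GC content minus that in the 10% with the lowest, with a prior of 2. GC content was that of the longest GENCODE M21 transcript and was known for 97.2% of tested genes. It ranged from -3.17 to 2.84, with 10 libraries beyond 1 in absolute value and 14 within. After this was seen, fits were added with GC deviation as a covariate, with a smooth GC offset (natural spline with 5 degrees of freedom), without the 10 libraries, and with the covariate plus a replicate-number block.

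Alternatives planned before the data were examined were: no filter, a filter of FPKM 5, an adjusted p under 0.01, an absolute log2 fold change of at least 1, median-of-ratios factors in edgeR, DESeq2 1.42.0, limma on log2(FPKM + 1) with depth scaling, the same with a pseudocount of 0.1, with median-of-ratios factors, with quantile normalization, without trend and with arrayWeights, a fit of only the groups compared, a block for replicate number, removal of each library in turn, removal of marker genes of other cell types, and the estimated correlation for lists. Where removal left 1 library in a group, that lone sample was assumed to vary like the other groups.

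The procedure was tested on simulated data. Of 100 genes given a 2-fold or 4-fold change, 4% and 39% were recovered for the LPS response at D1, 3% and 51% at D49, 6% and 51% for the D1 to D49 control difference, 7% and 55% from D21 to D49, and 0% and 18% for the difference in LPS response; 1 to 3 of 11574 unchanged genes passed. With a simulated GC slope and no other change, 2023 genes passed between D1 and D49 controls without the covariate and 0 with it. The slopes were those of the covariate fit, so the 0 follows largely from the design of the simulation. It does not show that the covariate removes GC bias of another shape. Of 20 simulated lists of 30 genes, the list shifted 1.5-fold gave an adjusted p of 1.3e-05 by camera, and 0 of the others passed.

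No outlier test within groups was made, since groups had 2 or 3 libraries; single libraries were weighed by arrayWeights and by removal. Genes below the filter, transcript isoforms and gene ontology terms were not analysed here.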

Results

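Alveolar macrophages were taken from mice at 5 postnatal ages from 1 to 49 days (D1 to D49) and kept for 4 h with LPS or in medium without it (control). RNA-seq covered 24 libraries in 10 groups. Control and LPS libraries numbered 2 and 3 at D1, 3 and 2 at D3, 2 and 2 at D7, 3 and 2 at D21, and 3 and 2 at D49. Library totals were 15.8 to 23.3 M counts, and 11774 genes were tested. Levels are mean CPM ± SD, fold changes are log2 values ± SE, and adjusted p-values come from edgeR QL with Benjamini-Hochberg correction. Among the named genes that passed, all libraries of the higher group lay above all libraries of the lower group in 217 of 218 gene and comparison pairs. For genes not selected by a test, chance gives this in 10% to 33.3%, depending on group size; these genes were selected for passing, so that share is no comparison for them. The exception was Gapdh between D1 and D49 controls.

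Libraries differed in how GC-rich and GC-poor transcripts were represented. Principal component 1 held 51.3% of variance, and its loadings followed GC content across genes (Spearman correlation -0.71). GC deviation, the log2 offset of GC-rich against GC-poor genes, was beyond 1 in 10 libraries. These included D1 control library 2 (2.28), D1 LPS libraries 2 and 3 (2.84 and 2.36), D21 control libraries 2 and 3 (-2.14 and -1.67), and D49 control libraries 2 and 3 (-2.08 and -3.17). All libraries numbered 1 lay between -0.21 and 0.36. Fits with GC deviation as a covariate, and fits of the 14 libraries within 1, are given for many of the results they changed. A gene or list that did not pass is one that missed the threshold with all libraries and no covariate, and list tests are without the covariate unless it is named. The 14 libraries leave 1 library each in D1 control, D1 LPS, D3 LPS, D21 control, D49 control and D49 LPS.

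**Figure D1:**
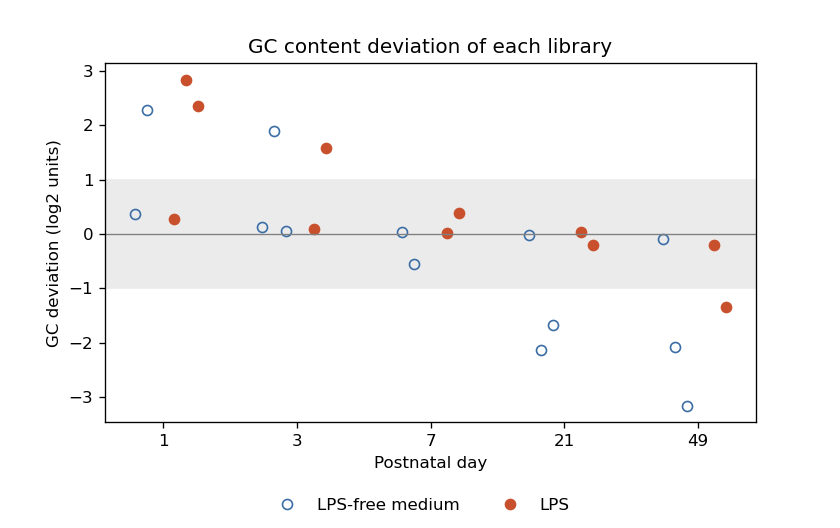
GC deviation (log2) of each library by group; each point is 1 library and the grey band marks values within 1. Deviations were positive at D1 and D3 (up to 2.84) and mostly negative at D21 and D49 (down to -3.17).

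LPS raised cytokine, chemokine and interferon response transcripts in D1 macrophages (3 LPS and 2 control libraries). Il6, an acute-phase cytokine, rose from 60.3 ± 16.1 to 1060 ± 246 CPM (log2 fold change 4.13 ± 0.38, adjusted p = 1.8e-06). Il1b, the inflammasome substrate, rose from 994 ± 61.6 to 5840 ± 264 CPM (2.56 ± 0.30, adjusted p = 3.7e-05). The interferon-inducible chemokine Cxcl10 rose from 149 ± 35.4 to 2480 ± 643 CPM (4.06 ± 0.45, adjusted p = 1.7e-05). Ifnb1, encoding interferon beta, rose by 3.56 ± 0.74 (adjusted p = 0.005) and the anti-inflammatory cytokine Il10 by 3.15 ± 0.63 (adjusted p = 0.004). Tnf was 1520 ± 702 CPM in control and 4970 ± 2010 CPM with LPS and did not pass (1.70 ± 0.75, adjusted p = 0.28). It passed with the GC covariate (1.35 ± 0.35, adjusted p = 0.0089) and not in the 14 libraries (1.47, 0.14). Cd14, the LPS co-receptor, did not pass (1.37 ± 0.46) but did with the covariate (1.12 ± 0.21, adjusted p = 0.00033), in the 14 libraries (0.022) and by DESeq2 (0.019). Also not passing were Tlr4, the LPS receptor (-0.62 ± 0.33), the scavenger receptor Marco (0.99 ± 0.77), the mannose receptor Mrc1 (-0.26 ± 0.27), the IgG receptor Fcgr1 (0.75 ± 0.69), the sialic acid lectin Siglecf (-0.23 ± 0.26), the transcription factor Pparg (-0.21 ± 0.23) and the proliferation marker Mki67 (-0.44 ± 0.29).

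By edgeR QL, 667 genes passed at D1, of which 440 rose and 227 fell. The count was 1441 (814 up, 627 down) with the GC covariate and 829 in the 14 libraries, and limma on log2(FPKM + 1) split it into 450 and 417. It was 277 without D1 control library 1 and 299 without D1 control library 2. Of 25 proinflammatory cytokine and chemokine genes, 19 rose and 0 fell (21 and 0 over the list alone; camera adjusted p = 1.05e-40). The largest rises in it were the monocyte attractant Ccl7 (4.89 ± 0.73), the cytokine subunit Il27 (4.87 ± 0.98) and the TNF family ligand Tnfsf15 (4.58 ± 0.44). Of 31 interferon response genes, 28 rose and 0 fell (29 and 0 alone; 2.3e-89), led by the ubiquitin-like modifier Isg15 (4.81 ± 1.35, adjusted p = 0.041), Oasl1 (4.55 ± 0.97), Ifit1 (4.51 ± 0.39) and the guanylate-binding protein Gbp5 (4.26 ± 0.33).

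Among 33 negative regulators of Toll-like receptor signalling at D1, 5 rose and 0 fell (10 and 1 alone; camera adjusted p = 1.93e-05), among them the itaconate enzyme Acod1 (1.55 ± 0.24) and the interleukin 1 antagonist Il1rn (1.53 ± 0.20). Of 25 tolerogenic genes 7 rose and 0 fell (2.05e-06), including Tgfb2 (3.04 ± 0.38) and the chemokine Ccl22 (2.53 ± 0.33). Of 38 proliferation genes 2 rose and 7 fell (2 and 17 alone; 2.05e-06). The mitotic kinesin Kif11 fell by 1.55 ± 0.35 while Ccne1, a cyclin, rose by 1.62 ± 0.37. Antigen presentation (4 rose of 22; 1.64e-05), oxidative burst (3 of 18; 0.0037), lipid handling (1 rose, 3 fell of 34; 0.0392), cholesterol biosynthesis (1 fell of 23; 0.00928) and fetal growth genes (1 rose, 1 fell of 6; 0.0474) passed at the preset correlation. Their adjusted p with an estimated correlation were 0.186, 0.186, 0.323, 0.18 and 0.186, and with the covariate as well 0.00201, 0.00656, 0.0114, 0.113 and 0.279. Members of these lists that passed included the costimulator Cd40 (3.27 ± 0.52), the hepcidin gene Hamp (4.31 ± 0.61), the nitric oxide synthase Nos2 (4.02 ± 0.58) and the desaturase Scd2 (-1.79 ± 0.24). The other 12 lists did not pass, from 0.0573 for monocyte markers to 0.878 for alveolar macrophage identity. For the latter the median (-0.10) and the test pointed down while the mean was 0.06. For stress genes the median was 0.08 against a mean of -0.09.

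Among the 6 largest falls at D1 were the activating receptor Cd300lb (-2.58 ± 0.28, adjusted p = 1.3e-05), the arrestin Arrb1 (-2.40 ± 0.37), the amino acid transporter Slc43a2 (-2.38 ± 0.44), the glycosyltransferase Gcnt1 (-2.10 ± 0.31) and the membrane protein Megf9 (-2.08 ± 0.35). A fit of the D1 libraries alone ended the calls of Slc43a2, Gcnt1, Megf9, Isg15, Oasl1, Acod1, Il1rn, Kif11, Ccne1 and Scd2, and a pseudocount of 0.1 that of Isg15. Without D1 control library 1 the calls ended for Il27 (4.54, adjusted p = 0.096), Isg15 (4.07, 0.4), Oasl1 (3.84, 0.13), Kif11 (-1.21, 0.21), Ccne1 (1.71, 0.11) and Ifnb1 (3.63, 0.082). Removing D1 control library 2 ended those of Slc43a2 (-1.89, 0.058), Il27 (5.3, 0.054), Isg15 (6.41, 0.11), Ccne1 (1.54, 0.15), Il10 (2.73, 0.099) and Ifnb1 (3.5, 0.089). It also moved Hamp to 5.34 and Oasl1 to 5.98. Without D1 LPS library 2 they ended for Isg15 (4.28, 0.083) and Kif11 (-1.25, 0.1), and without D1 LPS library 3 for Isg15 (4.64, 0.082). Quantile normalization ended the call of Kif11 and arrayWeights that of Ccne1.

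**Figure D2:**
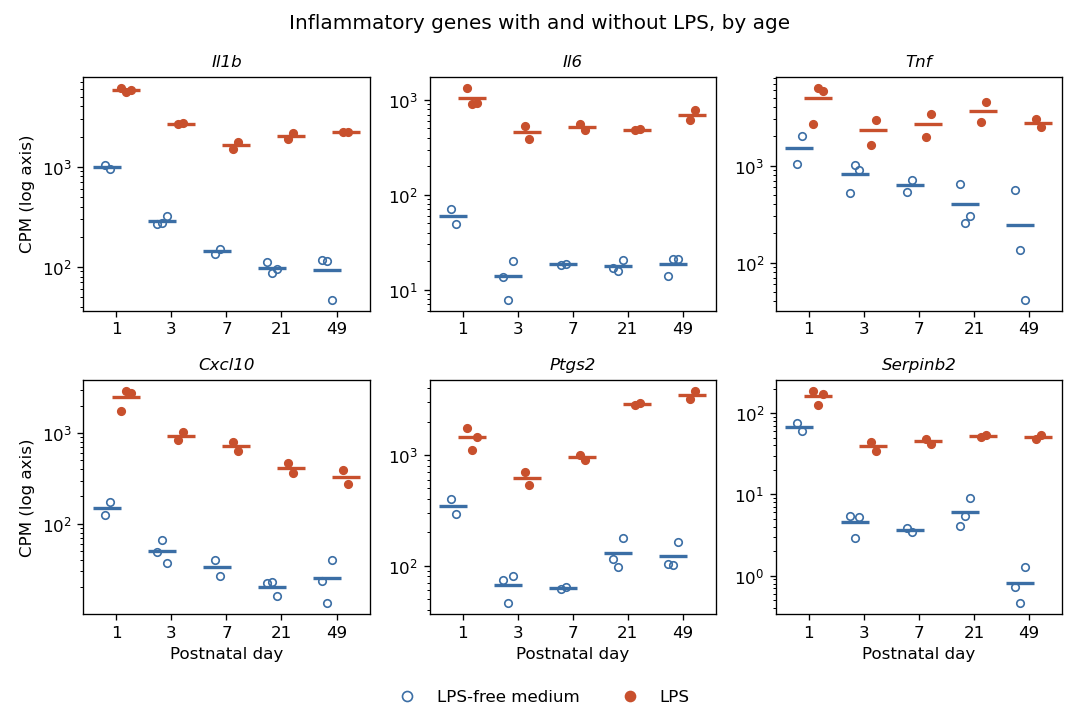
CPM (log axis) against postnatal day for Il1b, Il6, Tnf, Cxcl10, Ptgs2 and Serpinb2; open blue circles are control libraries, filled red circles LPS libraries, and bars group means. Control Il1b was 994 CPM at D1 and 92.6 CPM at D49, against 5840 and 2210 CPM with LPS.

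The 6 largest rises with LPS at D1 were genes of exocrine glands rather than macrophage genes. The secretoglobin Scgb2b27 was absent from both D1 control libraries and reached 195 ± 42.3 CPM in the 3 LPS libraries, at least 1530-fold. Prol1, a tear and saliva protein gene, reached 172 ± 62 CPM (at least 1340-fold) and Pip, a secretory actin-binding protein gene, 110 ± 32.2 CPM (at least 862-fold). Scgb1b27 was 0.0193 ± 0.0273 and 93.8 ± 10.9 CPM, the mucin-like Mucl2 0.349 ± 0.162 and 441 ± 161 CPM, and Scgb2b26 0.0579 ± 0.0819 and 63.2 ± 14.3 CPM. At D49 the same genes ran the other way. Mucl2 fell from 739 ± 330 CPM in control to 3.44 ± 0.0614 CPM with LPS, Prol1 from 306 ± 75.5 to 2.77 ± 0.347 and Scgb2b27 from 258 ± 136 to 0.633 ± 0.805. Pip fell from 206 ± 98 to 0.754 ± 0.975, Scgb2b26 from 84.3 ± 22.8 to 0.182 ± 0.167 and Scgb1b27 from 74.1 ± 23 to 0.501 ± 0.199. The sum of the 6 genes was 0.426 ± 0.271 CPM in D1 control, 1080 ± 234 in D1 LPS, 328 ± 64.6 in D3 LPS, 530 ± 12.7 in D7 LPS, 1630 ± 144 in D21 control, 1670 ± 623 in D49 control and 8.28 ± 1.46 in D49 LPS. Some of these genes are close paralogs, so reads may be shared between them.

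**Figure D3:**
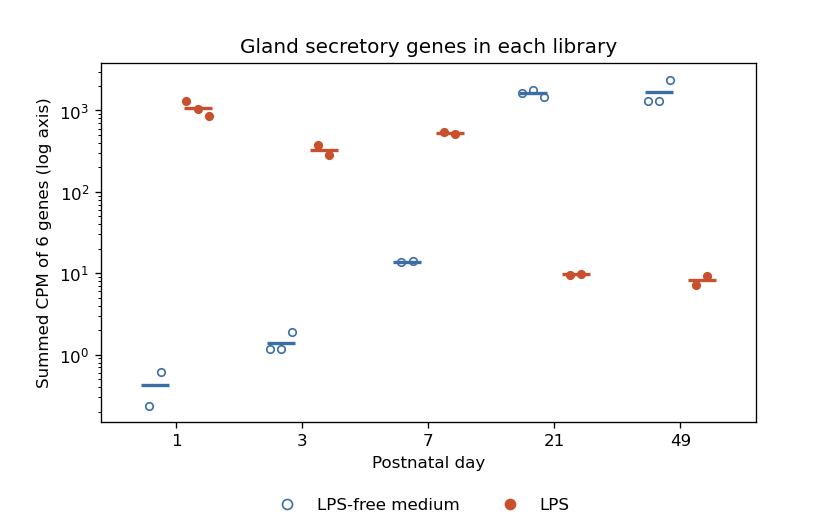
Summed CPM (log axis) of Scgb2b27, Prol1, Pip, Scgb1b27, Mucl2 and Scgb2b26 in each library by postnatal day; open blue circles are control and filled red circles LPS libraries. The sum was high with LPS at D1, D3 and D7 and high in control at D21 and D49.

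At D49 (2 LPS and 3 control libraries) LPS again raised cytokines and interferon response genes. Il1b rose from 92.6 ± 40 to 2210 ± 9.14 CPM (4.57 ± 0.29, adjusted p = 2e-08), Il6 from 18.8 ± 4.14 to 695 ± 112 CPM (5.21 ± 0.34, 2.7e-08) and Tnf from 243 ± 275 to 2760 ± 334 CPM (3.50 ± 0.72, 0.003). Cxcl10 rose by 3.70 ± 0.39 (3.7e-06), Il10 by 4.15 ± 0.60 (0.00012), Ifnb1 by 4.37 ± 0.76 (0.00066) and Cd14 by 2.14 ± 0.43 (0.0024). Tlr4 fell by 1.24 ± 0.34 (0.025). Marco (1.60 ± 0.74) did not pass but did with the GC covariate (1.32 ± 0.28, adjusted p = 0.0008), with the smooth GC offset (0.0056) and without a filter (1.3e-05). In the 14 libraries it did not (0.74, 0.52). Not passing were Mrc1 (0.06 ± 0.27), Fcgr1 (1.32 ± 0.70), Siglecf (-0.58 ± 0.27), Pparg (-0.29 ± 0.24) and Mki67 (-0.23 ± 0.29).

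The 6 largest rises at D49 were the interferon-inducible DNA sensor Ifi202b (0.139 ± 0.131 to 15.7 ± 7.71 CPM, adjusted p = 2e-05), the RANK ligand Tnfsf11 (0.251 ± 0.434 to 23.2 ± 3.17 CPM, 0.011), the protease inhibitor Serpinb2 (5.97 ± 0.41, 2.8e-08), Tnfsf15 (5.89 ± 0.41), and the chemokines Ccl4 (5.70 ± 0.86) and Ccl5 (5.43 ± 0.49). The 6 largest falls were the gland genes above. In all 1203 genes passed by edgeR QL, 617 up and 586 down. With the covariate 2288 passed, and 1359 in the 14 libraries. The count was 2049 without D49 control library 1, 593 without D49 LPS library 1 and 613 without D49 LPS library 2.

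Of 25 proinflammatory genes 21 rose and 0 fell at D49 (camera adjusted p = 9.38e-43). Of 31 interferon response genes 22 rose and 0 fell (25 and 0 alone; 2.79e-40), among them Gbp5 (5.33 ± 0.30) and Ifit1 (4.65 ± 0.34). Negative regulators (10 rose, 2 fell of 33, 13 and 2 alone, 1.47e-05) included the cytokine signalling suppressor Socs3 (3.06 ± 0.61). Tolerogenic genes (7 rose, 1 fell of 25, 0.000377) included Tgfb2 (3.82 ± 0.34) and the transcription factor Irf4 (3.40 ± 0.34). Proliferation genes (2 rose, 16 fell of 38; 1.53e-05) included Ccne1 (3.29 ± 0.37) and the centromere protein Cenpf (-2.67 ± 0.46). Of 30 phagocytic and scavenger receptors 7 fell and 1 rose, although the list did not pass (0.089). With the covariate 12 fell and 3 rose and the list passed at the preset (0.0155) but not at an estimated correlation (0.154), as at D7 (0.0204 and 0.189) and D21 (0.0178 and 0.173). Among them were the beta-glucan receptor Clec7a (-1.97 ± 0.37) and the collectin Colec12 (-1.52 ± 0.28) down and the integrin Itgav up (1.98 ± 0.28). Lipid handling (1 rose, 7 fell of 34; 0.00629), cholesterol biosynthesis (4 fell of 23; 11 alone; 0.00629), oxidative burst (5 rose of 18; 0.00081), antigen presentation (4 rose of 22; 0.00291) and fetal growth genes (2 rose, 1 fell of 6; 0.00767) passed at the preset correlation. The estimated correlation gave 0.25, 0.125, 0.125, 0.324 and 0.125, and with the covariate as well 0.00135, 0.107, 0.0079, 0.0357 and 0.154. In these lists Scd2 fell by 2.91 ± 0.27, the cholesterol acyltransferase Soat1 by 1.99 ± 0.26, and Hamp rose by 4.38 ± 0.53 and Cd40 by 3.72 ± 0.48. The other lists did not pass (0.067 to 0.98).

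DESeq2 ended the call of Tnfsf11 at D49. A fit of the D49 libraries alone ended those of Clec7a, Colec12, Ifnb1 and Tlr4, and quantile normalization that of Tlr4. Without D49 control library 1, Tnf moved to 4.98, Ifnb1 to 4.97 and Hamp to 5.02; without D49 control library 3 the Tlr4 call ended (-0.85, adjusted p = 0.18). Without D49 LPS library 1 the calls of Clec7a (-1.88, 0.054) and Tlr4 (-1.13, 0.27) ended, as did that of Tlr4 without D49 LPS library 2 (-1.47, 0.12).

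Il1b rose with LPS by 3.23 ± 0.28 at D3 (adjusted p = 2.4e-07), 3.51 ± 0.33 at D7 (7.6e-07) and 4.37 ± 0.29 at D21 (1.6e-08). Il6 rose by 5.05 ± 0.34, 4.81 ± 0.40 and 4.77 ± 0.34 at these ages and Cxcl10 by 4.21 ± 0.39, 4.42 ± 0.47 and 4.36 ± 0.40. Il10 rose by 4.13 ± 0.63, 3.66 ± 0.70 and 4.61 ± 0.61, Ifnb1 by 4.09 ± 0.70, 4.58 ± 0.84 and 3.89 ± 0.73, and Cd14 by 1.85 ± 0.43, 2.52 ± 0.50 and 2.90 ± 0.44. Tnf passed at D21 (3.19 ± 0.72, 0.005) but not at D3 (1.51 ± 0.69; 1.32 ± 0.33 and 0.0054 with the covariate) or D7 (2.10 ± 0.80; 1.72 ± 0.38 and 0.0013). Tlr4 fell by 1.57 ± 0.37 at D7 (0.0087) and by 1.56 ± 0.35 at D21 (0.0049), with -0.80 ± 0.34 at D3. Marco (0.92, 1.50 and 2.03), Mrc1 (-0.18, -0.04 and -0.15), Fcgr1 (0.06, 0.93 and 1.26), Siglecf (-0.34, -0.42 and -0.60), Pparg (-0.01, -0.50 and -0.73) and Mki67 (-0.41, -0.37 and -0.49) did not pass at D3, D7 or D21. With the covariate Marco passed at D7 (0.015) and D21 (0.00095, but 0.11 in the 14 libraries), Pparg at D21 (-0.75, 0.022) and Tlr4 at D3 (0.02). DESeq2 also brought Pparg past the threshold at D21 (0.022), and the 14 libraries did so for Pparg at D21 (0.033) and for Tlr4 at D3 (0.018), Marco at D7 (0.018) and Mki67 at D7 (0.037). Without D3 control library 3, Il10 moved to 3.54. The Cd14 call at D3 ended without D3 control library 1 (1.68, 0.059), D3 control library 3 (1.64, 0.053) or D3 LPS library 2 (1.48, 0.17). The Tlr4 call at D7 ended without D7 control library 2 (-1.52, 0.057), D7 LPS library 1 (-1.71, 0.054) or D7 LPS library 2 (-1.45, 0.12), and at D21 without D21 LPS library 2 (-1.54, 0.097). Ifnb1 moved to 5.41 without D7 control library 2 and to 4.65 without D21 control library 1.

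At D3, 825 genes passed (522 up, 303 down; 2 LPS and 3 control libraries), at D7 1132 (606 and 526; 2 and 2) and at D21 1590 (797 and 793; 2 and 3). With the GC covariate 1745, 2080 and 2507 passed, and in the 14 libraries 1557, 3327 and 2452. Limma on log2(FPKM + 1) split the D3 count into 487 and 535 and the D7 count into 545 and 939. Without D3 LPS library 1 or 2 the counts were 427 and 414. Without D7 control library 1 or 2 they were 609 and 603, without D7 LPS library 1 or 2 629 and 620, and without D21 LPS library 1 or 2 781 and 683. The largest rises at D3 were Pip (0.0139 ± 0.0241 to 28.5 ± 12.6 CPM), Prol1 (9.10 ± 0.53) and Scgb1b27 (0.0858 ± 0.109 to 29.6 ± 0.4 CPM). The largest falls there were the cannabinoid receptor Cnr2 (-3.83 ± 0.47), the transcription factor Fli1 (-3.04 ± 0.37) and the potassium channel Kcnj2 (-2.84 ± 0.41). At D7 they were Ifi202b (0.152 ± 0.142 to 23.2 ± 1.07 CPM), Ifit1 (6.95 ± 0.45) and Ccl5 (6.85 ± 0.63). Falling most were the pentraxin Apcs (4.99 ± 0.513 to 0.101 ± 0.143 CPM), Cnr2 (24 ± 0.344 to 1.03 ± 0.484 CPM) and the helicase Zranb3 (-4.34 ± 0.43). At D21 Ifit1 (6.16 ± 0.36), Isg15 (3.2 ± 3.57 to 219 ± 11 CPM) and Ccl4 (10.6 ± 8.84 to 690 ± 187 CPM) rose most. The largest falls at D21 were muscle genes without a count in the LPS libraries: Myh4 (64.1 ± 91.3 CPM in control, at least 364-fold), Ckm (15.5 ± 18.9, at least 87.9-fold) and Tnnc2 (4.32 ± 5.82, at least 24.5-fold). These muscle calls rest on uneven control libraries and ended without D21 control library 1 (adjusted p = 0.054, 0.053 and 0.094), D21 LPS library 1 (0.17, 0.16 and 0.21) or D21 LPS library 2 (0.18, 0.17 and 0.21).

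At D3, D7 and D21 interferon response genes rose in 28, 27 and 28 of 31 (camera adjusted p = 1.44e-117, 1.42e-105 and 1.81e-68) and proinflammatory genes in 18, 18 and 21 of 25 (3.73e-53, 2.3e-36 and 1.48e-40), with 0 falling. Proliferation genes fell in 10, 18 and 16 of 38 (8.5e-07, 8.12e-10 and 4.25e-08). Negative regulators rose in 8, 8 and 13 of 33 (6.93e-06, 3.29e-05 and 4.03e-06) and tolerogenic genes in 7 of 25 at each age (5.22e-06, 0.000258 and 0.00154). Monocyte markers rose in 3 of 10 at each age (0.0165, 0.0298 and 0.00837), with an adjusted p of 0.0744 at D7 with an estimated correlation. Oxidative burst, fetal growth, lipid handling and antigen presentation genes passed at each of these ages, and cholesterol biosynthesis at D21 (0.0308), at the preset correlation. The estimated correlation gave 0.0671 to 0.385 and 0.237. With the covariate as well, oxidative burst (0.00168, 0.00338 and 0.00332 at D3, D7 and D21) and lipid handling (0.021, 0.0108 and 0.00424) passed, and antigen presentation did at D3 and D7 (0.021 at each) but not at D21 (0.0587). Toll-like receptor 4 pathway genes passed at these ages only with the covariate, at D7 (0.0331, and 0.0453 estimated) and D21 (0.0179, and 0.0322 estimated). Across all 5 ages 267 genes rose and 132 fell at every age (496 and 368 with the covariate), out of 2035 that passed at any age. Between D1 and D49, 280 genes rose in both responses (23.1 expected), 171 fell in both (11.3 expected) and 12 ran opposite. These responses have separate controls. Pearson correlation of fold changes across genes was 0.38 between D1 and D49, 0.53 between D1 and D3, and 0.64 between D21 and D49.

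**Figure D4:**
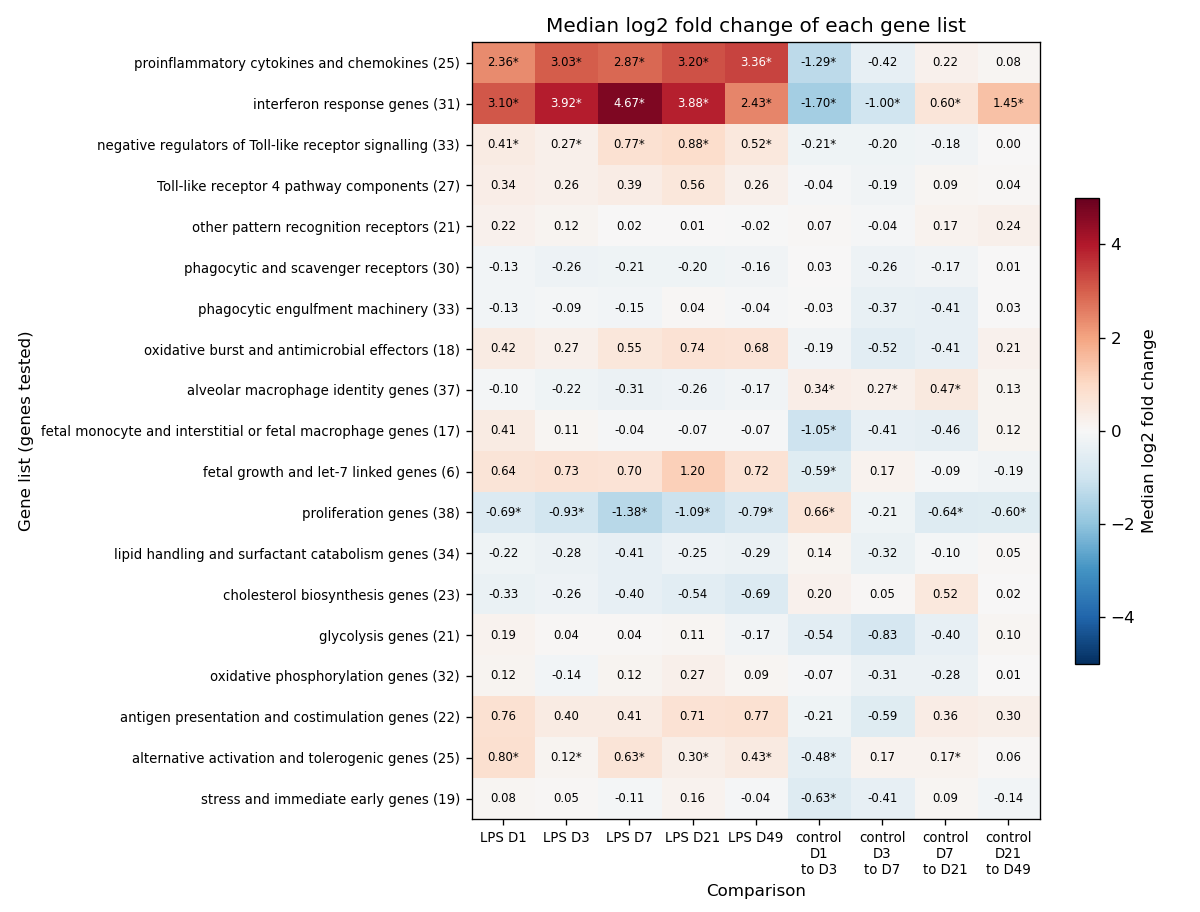
Median log2 fold change of the 19 pathway lists (vertical) in the LPS response at each age and in each control step (horizontal); an asterisk marks a camera adjusted p under 0.05 with both the preset and the estimated correlation. Interferon response genes rose with LPS at all ages (median 3.10 at D1, 2.43 at D49) and fell in controls from D1 to D3 (-1.70).

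Outside the gland set, Serpinb2, Ptgs2 and Il1b rose more with LPS at D49 than at D1 (10 libraries). Serpinb2 had a D49 response larger by 4.69 ± 0.51 (adjusted p = 3.8e-05). Its control levels were 67.1 ± 10.7 CPM at D1 and 0.821 ± 0.419 at D49, against 162 ± 31.1 and 51.1 ± 4.11 with LPS. The prostaglandin synthase Ptgs2 had a response larger by 2.77 ± 0.42 (0.0028), from 346 ± 73 to 1440 ± 325 CPM at D1 and from 123 ± 34.7 to 3510 ± 390 at D49. The Il1b response was larger by 2.02 ± 0.38 (0.028). In the other direction the 6 gland genes had the largest differences, with adjusted p from 2.5e-11 (Mucl2) to 5e-08 (Scgb2b27 and Pip). Tnf (1.80 ± 0.98) and Il6 (1.08 ± 0.44) did not pass, but did with the GC covariate (2.08 ± 0.47, adjusted p = 0.016, and 1.21 ± 0.29, 0.024); in the 14 libraries they did not (0.99, 1, and 1.16, 0.3). Nor did Il10 (1.01 ± 0.80), Cxcl10 (-0.36 ± 0.53), Ifnb1 (0.80 ± 0.96), Tlr4 (-0.63 ± 0.47), Cd14 (0.77 ± 0.61), Marco (0.60 ± 1.05), Mrc1 (0.33 ± 0.38), Fcgr1 (0.57 ± 0.98), Siglecf (-0.35 ± 0.37), Pparg (-0.08 ± 0.33) and Mki67 (0.20 ± 0.41).

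In all 24 genes passed for this difference, 4 with a positive and 20 with a negative difference, D49 response minus D1 response (191, 72 and 119, with the covariate; 21 in the 14 libraries). Of simulated 2-fold and 4-fold differences of this kind 0% and 18% were recovered. The count was 12 without D1 control library 2, 38 without D49 control library 1, 15 without D49 LPS library 1 and 37 without D49 LPS library 2. Limma on log2(FPKM + 1) gave 46 and 48, median-of-ratios factors on FPKM 61 and 78, and quantile normalization 26 and 45. The proinflammatory list had a larger response at D49 (median 0.91; 2 genes higher, 0 lower; 3 and 3 alone; camera adjusted p = 3.57e-05), and the interferon list a smaller (median -0.63; 0 and 1; 1 and 6 alone; 1.42e-05). In level, proinflammatory genes were mostly lower at D49 than at D1, in control (2 rose, 14 fell of 25) and with LPS (5 rose, 13 fell). The other 20 lists did not pass (0.35 to 0.91). Across all 5 ages the F test gave 70 genes (304 with the covariate, 100 in the 14 libraries). It gave 41 and 45 without D1 control library 1 or 2, 36 and 40 without D7 control library 1 or 2, 40 without D7 LPS library 1 and 42 without D21 LPS library 2.

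The Il1b difference was fragile. Its call ended in the fit of the 4 groups alone, in the 14 libraries and with a pseudocount of 0.1. It also ended without D1 control library 1 (1.95, adjusted p = 0.15) or 2 (2.08, 0.099), D1 LPS library 1 (2.05, 0.065), 2 (1.92, 0.075) or 3 (2.01, 0.064), and D49 LPS library 1 (2.0, 0.12) or 2 (1.88, 0.087). The call of Ptgs2 ended in the fit of the 4 groups alone.

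Control libraries differed between D1 and D49 (2 and 3 libraries), and alveolar macrophage identity genes were higher as a list at D49. The chitinase-like Chil3 rose from 326 ± 80.2 to 25400 ± 8760 CPM (6.28 ± 0.38, adjusted p = 6.5e-09), Siglecf from 21.6 ± 2.55 to 212 ± 40.2 CPM (3.29 ± 0.30, 1e-06). Mrc1 rose from 608 ± 124 to 2590 ± 609 CPM (2.09 ± 0.29, 7.3e-05) and Pparg from 47.5 ± 3.85 to 107 ± 39.3 CPM (1.17 ± 0.24, 0.0025). The integrin Itgam fell by 3.62 ± 0.34 (1.2e-06), Il1b by 3.42 ± 0.28 (3.1e-07), Il6 by 1.69 ± 0.31 (0.00096), Cxcl10 by 2.56 ± 0.37 (0.00013) and Mki67 by 0.83 ± 0.28 (0.028). Ifnb1 was 1.21 ± 0.0753 CPM at D1 and 0.162 ± 0.141 CPM at D49 (-2.83 ± 0.77, 0.01). Tnf (-2.65 ± 0.71, 0.0097), Cd14 (-1.81 ± 0.43, 0.0055) and Fcgr1 (-2.78 ± 0.70, 0.0075) passed, but with the GC covariate they did not (-1.08 ± 0.40, -0.52 ± 0.27 and -1.16 ± 0.46). Not passing were Il10 (-1.28 ± 0.59), Tlr4 (0.70 ± 0.34) and Marco (-1.73 ± 0.74). Il10 passed with the covariate (-1.80 ± 0.58, adjusted p = 0.045) and by DESeq2 (0.03) but not in the 14 libraries (-2.64). Marco passed by DESeq2 (0.023) and in limma on log2(FPKM + 1) (0.019), but with the covariate its sign turned (0.34) and it did not pass.

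The 6 largest rises from D1 to D49 were Prol1 (at least 2390-fold), Scgb2b27 (at least 2010-fold), Pip (at least 1610-fold), the defensin-like Spag11b (absent at D1, 75.9 ± 49.8 CPM at D49, at least 593-fold), Scgb1b27 (0.0193 to 74.1 CPM) and Mucl2 (11.00 ± 0.57). The 6 largest falls were Serpinb2 (-6.36 ± 0.41, adjusted p = 1.7e-08), the NAD hydrolase Cd38 (30.5 ± 7.18 to 0.475 ± 0.318 CPM), the airway secretoglobin Scgb3a1 (7.3 ± 1.19 to 0.104 ± 0.18 CPM), the beta globin Hbb-bt (5.03 ± 3.8 to 0.0824 ± 0.101 CPM), the phosphatase Acpp (71.3 ± 12 to 1.42 ± 1.13 CPM) and the TNF family ligand Tnfsf9 (6.24 ± 1.27 to 0.104 ± 0.18 CPM).

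In all 5042 genes passed by edgeR QL, 2469 up and 2573 down, but fold change followed GC content across genes (Spearman correlation -0.67). With the GC covariate 1229 passed (704 up, 525 down, Spearman correlation -0.06), of which 958 had also passed without it in the same direction. In the 14 libraries 1482 passed. The count was 674 without D1 control library 2, 2642 without D49 control library 3 and 116 in the fit of these groups alone. In limma on log2(FPKM + 1) with depth scaling, where the median gene shifted by -0.3, the split was 1203 up and 3870 down. Genes whose call ended with the covariate included glycolytic Gapdh (-3.40 ± 1.19 without, 1.07 ± 0.67 with) and Eno1 (-3.20 ± 0.83 and -0.31 ± 0.36) and the sterol enzyme Fdps (-1.99 ± 0.71 and 0.17 ± 0.37).

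Of 37 alveolar macrophage identity genes 19 rose and 4 fell from D1 to D49 (19 and 5 alone; camera adjusted p = 1.7e-08; 20 and 0 with the covariate), led by Chil3, the potassium channel subunit Kcnip4 (0.128 ± 0.0175 to 10.5 ± 5.07 CPM), the lipid-binding Fabp1 (4.35 ± 0.68) and the receptor Flt1 (4.23 ± 0.29). Of 25 proinflammatory genes 2 rose and 14 fell (2 and 16 alone; 1.92e-05). Of 17 fetal monocyte and interstitial macrophage genes 1 rose and 9 fell (1 and 11 alone; 0.0011), including the transglutaminase F13a1 (9.03 ± 2.4 to 0.467 ± 0.314 CPM). Of 38 proliferation genes 1 rose and 20 fell (0.0011; 0 and 10 with the covariate). Among members of lists that did not pass, the RNA-binding fetal gene Igf2bp3 fell by 2.93 ± 0.28, the inhibitory IgG receptor Fcgr2b rose by 3.44 ± 0.27, the class II gene H2-Aa by 2.48 ± 0.60 and Ccl22 by 3.28 ± 0.34. The arginase Arg1 fell by 3.75 ± 0.48 and the matrix protein Thbs1 by 3.81 ± 0.43. Antigen presentation genes rose in 6 and fell in 4 of 22 without the covariate (0.543) and rose in 12 of 22 with it (3.41e-08).

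Several D1 to D49 lists passed at the preset correlation and not at an estimated one: interferon response (5 rose, 13 fell of 31; 0.0416), cholesterol biosynthesis (11 rose, 3 fell of 23; 0.0241), glycolysis (1 rose, 11 fell of 21; 0.00181), oxidative phosphorylation (3 rose, 14 fell of 32; 0.0244), oxidative burst (3 rose, 9 fell of 18; 0.0255), stress genes (1 rose, 10 fell of 19; 0.00335) and lung epithelial markers (1 rose, 5 fell of 9; 0.0355). With an estimated correlation these gave 0.0781, 0.188, 0.36, 0.38, 0.272, 0.0781 and 0.156. With the covariate glycolysis (0.871), oxidative phosphorylation (0.228) and oxidative burst (0.644) did not pass. With the covariate and an estimated correlation interferon response (0.0277), cholesterol biosynthesis (0.0277), stress (0.00725) and antigen presentation genes (0.00307) passed. The other lists did not pass (0.052 to 0.642). With the covariate neutrophil (2 rose, 5 fell of 9, 0.000901), monocyte (1 rose, 4 fell of 10, 0.041) and lung epithelial markers (1 rose, 3 fell of 9, 0.00311) were lower at the preset correlation. With an estimated correlation as well they did not pass (0.0703, 0.126 and 0.0545). A difference in cell composition between D1 and D49 libraries was therefore not excluded. For phagocytic receptors (9 rose, 11 fell of 30) the median was -0.22 and the mean -0.29 while the test pointed up. For tolerogenic genes (9 rose, 7 fell) the median was -1.02 and the mean -0.33 against an upward test.

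Alternatives ended more calls here. The fit of D1 and D49 controls alone ended those of Scgb3a1, Hbb-bt, Tnfsf9, Fabp1, H2-Aa, Il6, Cxcl10, Ifnb1, Tnf, Cd14, Mrc1, Fcgr1, Pparg, Mki67, Gapdh, Eno1 and Fdps. The 14 libraries ended those of Hbb-bt, Ifnb1, Tnf, Fcgr1, Eno1 and Fdps, and limma on log2(FPKM + 1), with a pseudocount of 0.1 or without trend that of Pparg. Removal of other cell type markers ended the Mki67 call, and 3 limma settings (median-of-ratios, quantile, arrayWeights) and the smooth offset that of Gapdh, the offset also that of Fdps. Leaving out D1 control library 1 ended the Mki67 call (-0.59, adjusted p = 0.18). Leaving out D1 control library 2 ended those of Tnf (-2.08, 0.14), Ifnb1 (-2.89, 0.071), Cd14 (-1.43, 0.11), Fcgr1 (-2.15, 0.13), Pparg (1.09, 0.063), Mki67 (-1.03, 0.095), Gapdh (-0.68, 0.76), Eno1 (-1.78, 0.23) and Fdps (-1.06, 0.43), and moved Fabp1 to 5.31. Without D49 control library 1 Tnf moved to -4.13, Fcgr1 to -4.18, Ifnb1 to -3.43, Gapdh to -4.53, Eno1 to -4.02, Fdps to -2.93 and H2-Aa to 1.66. Without D49 control library 2 or 3 calls ended for Gapdh (-3.01, 0.095; -3.11, 0.092) and Fdps (-1.64, 0.11; -1.74, 0.094), and without library 3 for Mki67 (-0.73, 0.13).

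**Figure D5:**
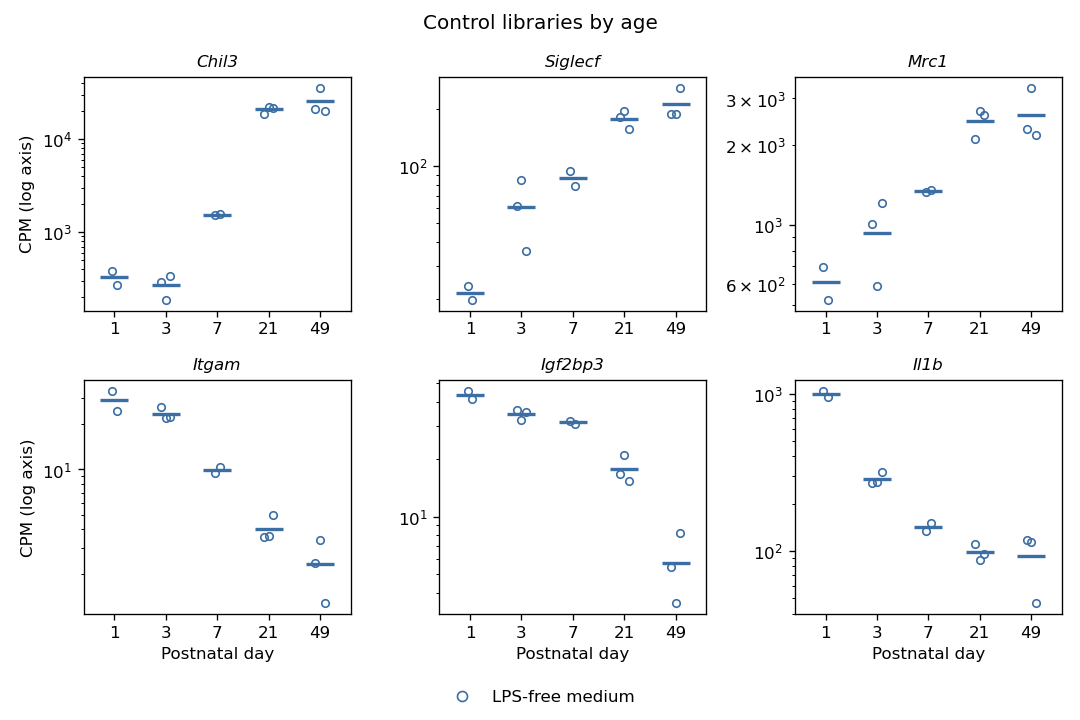
CPM (log axis) against postnatal day in control libraries for Chil3, Siglecf, Mrc1, Itgam, Igf2bp3 and Il1b; each circle is 1 library and bars are group means. Chil3 went from 326 CPM at D1 to 20800 CPM at D21, and Itgam from 29 to 2.35 CPM at D49.

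Between D1 and D3 controls (2 and 3 libraries) inflammatory transcripts fell. Serpinb2 fell by 3.88 ± 0.36 (adjusted p = 1.7e-05), Ptgs2 by 2.37 ± 0.30 (0.00018), Il6 by 2.13 ± 0.31 (0.00069), Il1b by 1.79 ± 0.27 (0.00084) and Cxcl10 by 1.56 ± 0.37 (0.034). Il10 fell from 1.9 ± 0.888 to 0.242 ± 0.211 CPM (0.017), while Siglecf rose by 1.49 ± 0.28 (0.0057). Liver-type plasma protein genes rose most, with fibrinogen gamma Fgg at 0.307 ± 0.162 and 10.7 ± 2.63 CPM, hemopexin Hpx at 0.462 ± 0.0568 and 11.1 ± 4.15 CPM and albumin Alb up by 4.22 ± 0.66. The X-inactivation transcript Xist fell from 346 ± 149 to 1.04 ± 0.958 CPM and Hbb-bt from 5.03 ± 3.8 to 0.296 ± 0.109 CPM. Given the Xist values, the pools may also differ in sex composition, which cannot be told apart from age in this step. Of 31 interferon response genes 1 rose and 18 fell (2 and 23 alone; camera adjusted p = 3.9e-63), of 25 proinflammatory genes 0 rose and 8 fell (0 and 16 alone; 2.1e-28), and of 38 proliferation genes 3 rose and 0 fell (9 and 0 alone; 7e-10). Also lower were fetal monocyte (7.52e-10), monocyte (5.03e-08), tolerogenic (8.97e-07), stress (2.21e-05), negative regulator (0.000152), epithelial (0.000774) and fetal growth genes (0.0011). Identity genes were higher (0.00265). Glycolysis (0.0076) and neutrophil markers (0.0245) were lower at the preset correlation (0.514 and 0.0517 estimated; 0.0982 and 0.0484 with the covariate as well).

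By edgeR QL 197 genes passed from D1 to D3, 71 up and 126 down (478 with the covariate, 362 in the 14 libraries; 45 and 130 in limma with median-of-ratios factors). Without D1 control library 1, 2 or D3 control library 1 the counts were 69, 94 and 104. Not passing were Tnf (-0.91 ± 0.69), Ifnb1 (-2.15 ± 0.70), Tlr4 (0.23 ± 0.33), Cd14 (-0.97 ± 0.43), Marco (0.23 ± 0.75), Mrc1 (0.62 ± 0.27), Fcgr1 (-0.05 ± 0.68), Pparg (0.51 ± 0.24) and Mki67 (0.87 ± 0.30). With the covariate Ifnb1 (0.022) and Cd14 (0.023) passed, and in the 14 libraries Cd14 (0.021), Mrc1 (0.04) and Mki67 (0.012). A fit of D1 and D3 controls alone ended the calls of Ptgs2, Il1b, Il6, Il10, Cxcl10, Siglecf and Hbb-bt. Quantile normalization ended that of Il10, the filter of FPKM 5 that of Hbb-bt, arrayWeights those of Hpx, Hbb-bt, Cxcl10 and Siglecf, and the 14 libraries those of Hpx, Hbb-bt and Siglecf. Without D1 control library 1 calls ended for Fgg (5.75, adjusted p = 0.1), Hpx (4.45, 0.36), Hbb-bt (-4.68, 0.078), Il10 (-2.38, 0.26), Cxcl10 (-1.78, 0.098) and Siglecf (1.62, 0.071). Without D1 control library 2 they ended for Fgg (4.65, 0.19), Hpx (4.7, 0.4), Hbb-bt (-2.96, 0.69), Cxcl10 (-1.29, 0.46) and Siglecf (1.38, 0.14). Without D3 control library 1, 2 or 3 they ended for Hpx (0.078, 0.073, 0.052) and Hbb-bt (0.17, 0.16, 0.15), and without library 1 or 3 for Cxcl10 (0.13, 0.16).

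From D3 to D7 (3 and 2 control libraries) Chil3 rose from 270 ± 76.3 to 1550 ± 17.7 CPM (2.52 ± 0.28, adjusted p = 0.00028). Mucl2 rose by 2.46 ± 0.37 (0.0079) and Colec12 by 1.49 ± 0.26 (0.024), while the interferon-inducible Rtp4 fell by 1.46 ± 0.27 (0.036) and the eosinophil-type ribonuclease Ear6 by 1.23 ± 0.23 (0.038). Of 31 interferon response genes 6 fell (11 alone; camera adjusted p = 3.28e-21) and of 37 identity genes 2 rose (0.000444). Oxidative burst (0.00671), glycolysis (0.00907) and engulfment genes (0.048) were lower and tolerogenic genes (0.048) higher at the preset correlation (0.256, 0.628, 0.468 and 0.101 estimated). In all 19 genes passed, 9 up and 10 down (79 with the covariate, 119 in the 14 libraries, 59 by DESeq2), and 586 had an unadjusted p under 0.05. The split was 12 and 8 in limma on log2(FPKM + 1), 11 and 5 with median-of-ratios factors and 12 and 4 with quantile normalization. In the fit of these groups alone 0 passed and 909 had an unadjusted p under 0.05. The always-reported genes did not pass, although Il1b did in the 14 libraries (-0.99, adjusted p = 0.019). Among them were Fcgr1 (-1.99 ± 0.74), Il10 (1.21 ± 0.68), Il1b (-1.01 ± 0.28), Marco (-0.93 ± 0.77) and Cd14 (-0.75 ± 0.45). Tnf, Il6, Cxcl10, Ifnb1, Tlr4, Mrc1, Siglecf, Pparg and Mki67 were -0.38, 0.42, -0.59, 0.06, -0.13, 0.52, 0.51, 0.34 and 0.23.

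The fit of D3 and D7 controls alone ended every D3 to D7 call, that of Chil3 included (2.58, adjusted p = 0.5). The count was 4, 11, 3 and 3 without D3 control library 1 or 2 or D7 control library 1 or 2. Colec12, Rtp4 and Ear6 lost their calls without D3 control library 1 (adjusted p = 0.11, 0.11 and 0.14), D3 control library 2 (0.082, 0.094 and 0.082), D7 control library 1 (0.32, 0.69 and 0.68) or D7 control library 2 (0.33, 0.58 and 0.77), Ear6 without D3 control library 3 (0.078) and Mucl2 without D7 control library 1 (0.18). Rtp4 and Ear6 also lost theirs in most limma fits, Rtp4 without marker genes, Ear6 without a filter and with median-of-ratios factors in edgeR, Colec12 with a pseudocount of 0.1 and Mucl2 with median-of-ratios factors on FPKM.

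From D7 to D21 (2 and 3 control libraries) Chil3 rose from 1550 ± 17.7 to 20800 ± 1930 CPM (3.75 ± 0.33, adjusted p = 3e-06). Xist rose from 0.682 ± 0.964 to 502 ± 139 CPM, Scgb2b26 from 0.486 ± 0.331 to 97.6 ± 41.8 CPM and Pip from 1.07 ± 0.347 to 175 ± 48.8 CPM. As from D1 to D3, age and the sex composition of the pools cannot be told apart in this step. The secreted glycoprotein Fstl1 fell by 2.17 ± 0.17 (1.1e-06), the phagosomal metal transporter Slc11a1 by 2.45 ± 0.47 (0.012) and the heparanase Hpse by 2.74 ± 0.52 (0.011). Identity genes (3 rose of 37; 7 alone; camera adjusted p = 1.17e-09), interferon response genes (3 of 31; 1.08e-06) and tolerogenic genes (5 of 25; 8.29e-05) were higher and proliferation genes lower (0 of 38 passing; 5 alone; 1.17e-09). Cholesterol biosynthesis (0.00362) and antigen presentation (0.00664) were higher and oxidative burst (0.033), fetal monocyte (0.0416), glycolysis (0.0418) and oxidative phosphorylation genes (0.0467) lower at the preset correlation (0.136, 0.5, 0.427, 0.136, 0.68 and 0.664 estimated). With the covariate antigen presentation passed at an estimated correlation too (0.000512). Siglecf (1.04 ± 0.27) and Mki67 (-1.01 ± 0.28) did not pass but did with the covariate (1.04 ± 0.26, adjusted p = 0.018, and -1.24 ± 0.21, 0.00047). Not passing were Mrc1 (0.88 ± 0.27), Pparg (0.72 ± 0.24), Tnf (-0.65), Il1b (-0.54), Il6 (-0.06), Il10 (0.15), Cxcl10 (-0.72), Ifnb1 (-0.31), Tlr4 (0.11), Cd14 (-0.35), Marco (-0.77) and Fcgr1 (-0.58).

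In all 129 genes passed from D7 to D21, 85 up and 44 down (372 with the covariate, 265 in the 14 libraries; 84 and 121 in limma on log2(FPKM + 1), where the median gene shifted by -0.16). Without D7 control library 1 or 2 the counts were 18 and 21, and without D21 control library 2 or 3 66 and 79. The calls of Hpse and Slc11a1 ended without D7 control library 1 (-2.93, adjusted p = 0.067; -2.46, 0.11), D7 control library 2 (-2.53, 0.17; -2.44, 0.13) or D21 control library 2 (-2.59, 0.062; -2.11, 0.055), and that of Slc11a1 without D21 control library 3 (-2.4, 0.058) and in the fit of these groups alone.

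From D21 to D49 (3 and 3 control libraries) interferon-linked genes rose again. The Schlafen genes Slfn8 and Slfn5 rose by 2.88 ± 0.31 (adjusted p = 8.1e-05) and 2.85 ± 0.28 (5.1e-05), Rtp4 by 2.36 ± 0.24 (5.1e-05) and Ifit1 by 1.86 ± 0.29 (0.0016). The liver-type secreted proteins Mup20 (-3.69 ± 0.61, 0.0028), Mup7 (-3.59 ± 0.84, 0.04) and Gc, the vitamin D carrier (-3.03 ± 0.55, 0.0052), fell. Of 31 interferon response genes 18 rose and 0 fell (21 and 0 alone; camera adjusted p = 5.74e-52), and proliferation genes were lower as a list with 0 passing (1.2e-09). Pattern recognition receptors were higher at the preset correlation (0.0249; 0.387 estimated). Mki67 (-0.92 ± 0.26) did not pass but did with the covariate (-0.98 ± 0.19, adjusted p = 0.0011), and in the 14 libraries it did not (-0.57, 0.19). Not passing were Tnf (-0.71), Il1b (-0.08), Il6 (0.08), Il10 (0.31), Cxcl10 (0.32), Ifnb1 (-0.43), Tlr4 (0.48), Cd14 (0.26), Marco (-0.27), Mrc1 (0.07), Fcgr1 (-0.17), Siglecf (0.26) and Pparg (-0.40). In all 148 genes passed, 91 up and 57 down (396 with the covariate, 136 in the 14 libraries; 71 and 111 in limma on log2(FPKM + 1)), with 90 without D21 control library 1 and 285 without D49 control library 1. None passed in the fit of these groups alone, where 349 genes had an unadjusted p under 0.05 and DESeq2 on all groups gave 242. Mup7 lost its call without any of D21 control library 1, 2 or 3 (adjusted p = 0.088, 0.079 and 0.087) or D49 control library 1, 2 or 3 (0.067, 0.1 and 0.17), with arrayWeights and in the 14 libraries. The fit of these groups alone ended every call named here.

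With LPS present, D1 and D49 macrophages (3 and 2 libraries) differed along the same identity axis. Chil3 was higher at D49 by 6.17 ± 0.32 (adjusted p = 1e-09), Siglecf by 2.95 ± 0.27 (8.5e-07), Mrc1 by 2.42 ± 0.27 (7.5e-06), Pparg by 1.09 ± 0.23 (0.0029) and Ptgs2 by 1.28 ± 0.29 (0.0047). Cxcl10 was lower by -2.91 ± 0.42 (0.0001), Il1b by -1.41 ± 0.28 (0.002), Serpinb2 by -1.67 ± 0.36 (0.0034), Ifnb1 by -2.03 ± 0.68 (0.032) and Fcgr1 by -2.21 ± 0.75 (0.034; -0.63 ± 0.44 and not passing with the covariate). Genes absent in D1 LPS were Spag11b (at least 300-fold), Tnfsf11 (at least 146-fold) and the langerin gene Cd207 (at least 78.8-fold). Hbb-bt (at least 53.3-fold) and the surface antigen Psca (at least 28.8-fold) were absent in D49 LPS, and Hbb-bs was 36.7 ± 11.4 CPM at D1 and 0.0321 ± 0.0454 at D49. Il6 (-0.61 ± 0.32) did not pass but did with the covariate (-1.26 ± 0.25, adjusted p = 0.00072) and in the 14 libraries (0.0057). Not passing were Tnf (-0.85 ± 0.72), Il10 (-0.28 ± 0.55), Tlr4 (0.07 ± 0.33), Cd14 (-1.04 ± 0.45), Marco (-1.13 ± 0.77) and Mki67 (-0.63 ± 0.29), which passed with the covariate (-1.16, adjusted p = 0.0017). With the covariate Marco passed in the opposite direction (1.04 ± 0.34, adjusted p = 0.034); in the 14 libraries it did not pass (0.18, 0.88).

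In all 3620 genes passed under LPS, 1954 up and 1666 down. With the covariate 1785 did, 1295 of them shared, and 1937 in the 14 libraries. Fold change followed GC content (Spearman correlation -0.61), and limma on log2(FPKM + 1) gave 1302 up and 2639 down. Identity genes (24 rose, 1 fell of 37; camera adjusted p = 5.18e-10) were higher. Interferon response (3 rose, 16 fell of 31; 2.35e-06), proliferation (3 rose, 21 fell of 38; 1.85e-05), fetal monocyte (1 rose, 7 fell of 17; 0.000148) and epithelial genes (1 rose, 6 fell of 9; 0.00237) were lower. Proinflammatory (5 rose, 13 fell; 0.0221), glycolysis (0.000982), oxidative phosphorylation (0.00447), stress (0.0055) and cholesterol genes (0.0317) passed at the preset correlation (0.137, 0.428, 0.426, 0.102 and 0.279 estimated), and stress genes with the covariate at an estimated correlation too (0.0189). The count was 1714 without D1 LPS library 2, 2219 without D1 LPS library 3, 1952 without D49 LPS library 1 and 775 without D49 LPS library 2. Calls ended without D49 LPS library 2 for Ptgs2 (1.08, adjusted p = 0.12), Pparg (1.03, 0.055) and Psca (0.063), without D49 LPS library 1 for Serpinb2 (-1.55, 0.051). They ended without any of D1 LPS library 2 or 3 or D49 LPS library 1 or 2 for Ifnb1 (0.064, 0.069, 0.12 and 0.15) and Fcgr1 (0.051, 0.1, 0.092 and 0.2). DESeq2 and the 14 libraries ended that of Psca, and the 14 libraries that of Fcgr1.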

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

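The tests of GC content, LPS acting alike at every age and neutrophils were chosen only after the results were seen; that of RNA from another source was set down before its value was known. What brought these results here was a tested difference between the LPS responses of 2 or more ages, except for the difference between D1 and D49 controls, which is weighed for its relation to GC content. The difference between the D1 and D49 responses passed in 24 genes, and a difference across all 5 ages in 70 genes, by edgeR QL with Benjamini-Hochberg correction.

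The gland genes differed most between the LPS responses at D1 and D49, with adjusted p of 2.5e-11 for Mucl2, 4e-10 for Prol1 and Scgb1b27, 8.2e-09 for Scgb2b26 and 5e-08 for Scgb2b27 and Pip. An action of LPS alike at every age was excluded by the pattern itself, since all 6 genes passed in opposite directions at D1 and D49. GC content was excluded as the whole cause: with the covariate the smallest absolute log2 fold change of the 6 genes at D1 or D49 was 6.66. RNA from a single other source, such as gland tissue or its secretions reaching some pools or libraries, remains possible but was not shown. The share of each gene in the sum of the 6 was taken over the 9 libraries of D1 LPS, D21 control and D49 control. The SD of its log2 had a median of 0.27 and was highest for Scgb1b27 (0.69) and Prol1 (0.45). This cannot decide the question, since these are groups where the genes were high and genes regulated together would also keep a steady ratio. Salivary Car6, given below, ran in the same directions as the 6 genes, higher with LPS at D1 and lower with LPS at D49. Unlike them it was present in D1 control, where they summed to 0.426 CPM. Smgc, also given below, was absent in D1 control and ran in these directions too. The LPS libraries of D3 and D7 were not part of this test. Where such RNA would have entered was not tested, and no biological explanation was tested.

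Larger LPS responses at D49 than at D1 were found for Serpinb2 (4.69 ± 0.51, adjusted p = 3.8e-05), Ptgs2 (2.77 ± 0.42, 0.0028) and Il1b (2.02 ± 0.38, 0.028). For each of the 3 genes the D1 control level exceeded the D49 control level: 67.1 against 0.821, 346 against 123 and 994 against 92.6 CPM. With LPS, Ptgs2 was higher at D49 (3510 against 1440 CPM, log2 difference 1.28 ± 0.29, adjusted p = 0.0047), so its control level alone does not account for its difference; Serpinb2 and Il1b were lower at D49. GC bias as the covariate describes it was excluded as the whole cause. The smallest of the 3 differences in LPS response with the covariate was 2.00 (Il1b, ± 0.32). GC bias of another shape was not excluded by this. In the 14 libraries the differences were 4.65 for Serpinb2, 2.73 for Ptgs2 and 1.59 for Il1b. Neutrophils bring their abundant transcripts together, and in the D1 control libraries S100a9 reached at most 1.37% of the Il1b FPKM and Ltf had a mean of 2.62 against 602 FPKM for Il1b. These low values run against neutrophils as the main source of Il1b. They cannot exclude them, since S100a9 and Ltf were chosen after the results were seen. S100a8 was higher at D1 (200 ± 82.5 FPKM) than at D49 (28.9 ± 14.3), which runs with that explanation. So does the neutrophil marker list from D1 to D49 controls, where 2 rose and 6 fell of 9. Its camera adjusted p was 0.087, and 0.000901 with the covariate, at the preset correlation (0.188 and 0.0703 estimated). A D1 macrophage that is already active before LPS could show a smaller fold change; cells at D1 before culture were not analysed here, so priming in the animal and activation during isolation could not be separated.

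Between D1 and D49 controls, 5042 genes passed and 958 of them passed with the same sign under the GC covariate. GC bias between libraries fits as a cause of calls that were lost, although this was not shown for single genes. In counts simulated with the GC slopes of the covariate fit and no other change, 2023 genes passed in this comparison. For the calls that were kept GC bias stays open. Of them 65.4% ran along the GC trend of all tested genes, and their median absolute log2 fold change went from 2.1 to 1.69 with the covariate. The share along the trend was 91.7% for the lost calls, but the covariate itself picked those out, so this contrast decides nothing. The share over all tested genes was not computed. Of the 958, 817 also passed with the same sign in the 14 libraries of small GC deviation, as did 486 of the lost calls, which runs against GC bias as their cause. But these libraries leave 1 control library at D1 and 1 at D49, both part of the fit of all libraries, and so add no independent evidence either way. Postnatal maturation, the difference in the design, remains a possible cause for Chil3 (5.72 ± 0.28 with the covariate), Siglecf (3.31 ± 0.33) and Il1b (-3.18 ± 0.28), which were among those kept.

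Mmp19, a matrix protease, had a more negative response at D49 than at D1 (difference -2.04 ± 0.28, adjusted p = 0.0011), falling from 331 ± 34.4 to 63.3 ± 2.38 CPM against 108 ± 8.63 and 84.5 ± 13.7 CPM at D1. H2-T24, a nonclassical class I gene, differed by -2.71 ± 0.43 (0.0044), Oas3, an antiviral synthetase, by -2.97 ± 0.49 (0.0067) and Samhd1, a nucleotide hydrolase, by -1.71 ± 0.34 (0.043). These genes, and the 8 of the next paragraph, were chosen after their values were seen. The fit of the 4 groups alone ended all of these calls, and the 14 libraries those of H2-T24 and Oas3. Without D1 control library 1 the call of Samhd1 (-1.86, adjusted p = 0.14) ended, and without D1 control library 2 those of Oas3 (-2.83, 0.099), H2-T24 (-2.58, 0.078) and Samhd1 (-1.58, 0.32). Without D49 LPS library 1 those of H2-T24 (-2.76, 0.074) and Samhd1 (-1.72, 0.34) ended and Oas3 moved to -3.6. The Samhd1 call also ended without D1 LPS library 1 (0.12) or 3 (0.091), D49 control library 2 (0.1) or 3 (0.12) or D49 LPS library 2 (0.13), without a filter and in 4 limma settings, and that of Oas3 with the smooth GC offset. The proinflammatory list (camera adjusted p = 3.57e-05) had a larger fold change at D49 and the interferon list (1.42e-05) a smaller one. Most proinflammatory members that passed between the ages were lower at D49, in control and with LPS. The larger fold change of that list is thus not a higher level.

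Other genes that passed were mostly of gland or liver type. Salivary Car6 was 7.92 CPM in D1 control and 30.4 with LPS, 13 and 0.15 at D49 (adjusted p = 5.1e-05), and Smgc was 0 and 7.37, then 7.95 and 0.0301 (3.2e-05). Of liver-type genes, Tdo2 was 0.284 and 6.31 CPM at D1, 1 and 1.07 at D49 (0.0044), Ugt2b35 0 and 2.45, 0.398 and 0.447 (0.012), Mbl1 0 and 1.99, 0.216 and 0.0301 (0.022), Fgb 0.489 and 7.27, 2.11 and 1.9 (0.04) and Slco1b2 0.0937 and 3.7, 0.607 and 0.734 (0.045). Zcchc24, an RNA-binding zinc finger gene, was 7.12 and 3.49 CPM, then 2.75 and 9.94 (2.89 ± 0.58, at the threshold with 0.05). The fit of the 4 groups alone ended these calls except those of Car6 and Smgc. The 14 libraries ended those of Ugt2b35, Mbl1, Fgb, Slco1b2 and Zcchc24, and several limma settings those of all 5 liver-type genes. Without D1 control library 1 calls ended for Fgb (0.23), Mbl1 (0.14), Ugt2b35 (0.11) and Zcchc24 (0.15), and without D1 control library 2 for these (0.28, 0.15, 0.15 and 0.22), Tdo2 (0.093) and Slco1b2 (0.21). Without D49 LPS library 1 they ended for Fgb (0.27), Mbl1 (0.14), Tdo2 (0.078), Slco1b2 (0.28) and Zcchc24 (0.24), and without D49 LPS library 2 for Zcchc24 (0.13). D1 LPS library 1 or 2 was needed for Fgb (0.091 and 0.061 without), Slco1b2 (0.098 and 0.075) and Zcchc24 (0.13 and 0.14), and D1 LPS library 3 for Fgb (0.064) and Slco1b2 (0.064). D49 control library 2 was needed for Fgb (0.1), Mbl1 (0.12), Slco1b2 (0.1) and Zcchc24 (0.12), library 3 for Fgb (0.085) and Slco1b2 (0.098), and library 1 for Zcchc24 (0.062).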

How the results depend on the processing

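The GC settings, the fit without 10 libraries and the block joined with the covariate were chosen after the data were seen; the other alternatives were set down before. Named genes that passed held their direction in nearly all alternatives. Of 8353 values for 351 gene and comparison pairs, 7722 kept their side of the threshold, 449 were no longer past it, 174 came past it and 8 reversed. A value was counted as reversed only where the gene passed in the main fit or in the alternative. Changes of sign in genes that passed in neither are among the 7722. With group sizes of 2 or 3 and library totals of 15.8 to 23.3 M counts, 0% to 7% of 2-fold changes were recovered in simulated data. Unless stated, the cause of a change was not tested. Results are ordered as LPS responses at D1, D3, D7, D21 and D49, control differences D1 to D49, D1 to D3, D3 to D7, D7 to D21 and D21 to D49, the D1 to D49 difference under LPS, the difference in LPS response and the F test over all ages.

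Gene values that reversed, counted in this way, were Gapdh between D1 and D49 controls (1.07 with the GC covariate, 1.02 with the replicate block and GC covariate, 0.33 in the 14 libraries), Fdps there (0.17 and 0.14 in the former settings), Marco under LPS (1.04 and 1.03, passing with adjusted p of 0.034 and 0.048) and Tlr4 under LPS (-0.64 with the smooth GC offset, passing with 0.011). Genes that passed in neither fit also changed sign with the GC covariate. Among them were Marco between D1 and D49 controls (-1.73 to 0.34) and Tnf from D3 to D7 (-0.38 to 0.28).

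With an adjusted p under 0.01, a stricter limit, counts were 358, 500, 674, 906 and 714 for the LPS responses, 1842, 97, 4, 46 and 80 for the control differences, 1391 under LPS and 34 for the F test. Without a filter they were 403, 205, 304 and 289 for the control steps, 109 for the difference in LPS response and 312 for the F test, which gave 43 with the filter of FPKM 5. DESeq2 gave 59, 258 and 242 from D3 to D7, D7 to D21 and D21 to D49, 97 for the difference in LPS response and 192 for the F test. With limma on log2(FPKM + 1) these were 205 (D7 to D21), 94 and 153, without trend 194, 74 and 135; median-of-ratios factors on FPKM gave 139 and 174 for the last pair, quantile normalization 71 for the difference, and a pseudocount of 0.1 gave 11 from D3 to D7. In limma with depth scaling the median of all genes was shifted by -0.16, -0.14 and -0.16 in the LPS responses at D1, D3 and D7, by -0.11 from D21 to D49, by -0.17 under LPS and by 0.13 in the difference in LPS response.

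With arrayWeights 1585, 4981, 4209 and 2126 genes passed for the LPS responses at D1, D7, D21 and D49, 114, 45 and 1517 from D1 to D3, D3 to D7 and D7 to D21, 7447 under LPS, 175 for the difference in LPS response and 418 for the F test. Fits of only the groups compared, with fewer libraries to estimate spread, gave 158, 442, 3073 and 305 for LPS at D1, D3, D7 and D49, 116, 20, 0, 44 and 0 for the control differences and 10 for the difference in LPS response. Median-of-ratios factors in edgeR and an absolute log2 fold change of at least 1 moved no count by over 1.5 times. Removal of marker genes of other cell types gave 8 from D3 to D7, with fewer genes tested.

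The replicate numbers were not taken as pairs, for which every pair correlation had to be over 0.1: 7 of 10 pair correlations were (0.07 to 0.83), although 18 of 20 libraries with a same-numbered partner correlated best with their own number. Same-numbered libraries thus shared structure that the main fit left out, and its LPS counts (667, 825, 1132, 1590 and 1203) depend on that choice. A replicate block gave counts of 1303, 1508, 2239, 2991 and 1932 for the LPS responses, 82 from D7 to D21, 70 for the difference in LPS response and 162 for the F test. The replicate block with GC covariate gave 2630, 2892, 3413, 2696 and 3254, 1231, 450, 62, 346 and 388, 1704, 776 and 959.

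The GC covariate gave 1441, 1745, 2080, 2507 and 2288 for the LPS responses, 1229, 478, 79, 372 and 396 for the control differences, 1785 under LPS, 191 and 304. The smooth GC offset gave 1146, 1322 and 1996 for LPS at D1, D3 and D49, 332, 44, 265 and 271 for the control steps, 73 and 171. Without 10 libraries of large GC deviation, counts were 1557, 3327 and 2452 for LPS at D3, D7 and D21, 1482, 362, 119 and 265 for D1 to D49 and the 3 steps up to D21, and 1937 under LPS, and the lists passing were 6 from D7 to D21, 7 from D21 to D49 and 7 for the difference in LPS response.

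With an estimated correlation the lists passing were 5, 6, 5, 6 and 5 for the LPS responses, 4 from D1 to D49, 2 from D3 to D7, 4 from D7 to D21 and 5 under LPS, where the preset correlation gave 10, 10, 10, 11 and 10, 11, 6, 10 and 10.

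Removing each library in turn gave 277 to 543, 414 to 892, 603 to 629, 683 to 1614 and 593 to 2049 genes for the LPS responses, 674 to 6505, 69 to 186, 3 to 13, 18 to 95 and 90 to 285 for the control differences, 775 to 4510 under LPS, 12 to 38 for the difference in LPS response and 36 to 89 for the F test. The lists passing were 7 to 11, 8 to 10, 8 to 10, 8 to 12 and 7 to 11, then 8 to 14, 12 to 14, 4 to 7, 6 to 9 and 2 to 5, then 8 to 10 and 2 to 2. Where 1 library remained in a group, that lone sample was assumed to vary like the other groups.

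Between D21 and D49 controls 148 genes and 3 lists passed; of 10 splits of these 6 libraries into 3 and 3, the real split included, 2 had as many genes and 4 as many lists. The highest other split by genes gave 164 genes and 4 lists. It set D21 control libraries 1 and 3 and D49 control library 1 (GC deviation -0.02, -1.67 and -0.1) against the others (-2.14, -2.08 and -3.17). Exchanging D21 control library 3 for library 2 left a similar GC contrast and gave 3 genes, so GC deviation was not shown to be the reason. With 10 splits no share under 0.05 is possible.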

Other observations

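Transcripts of other tissues varied between groups. Albumin Alb was 9.16 CPM in D1 control and 84.7 in D1 LPS, 170 and 147 at D3, 260 and 40.3 at D7, 209 and 267 at D21 and 32.8 and 36.1 at D49. The globin Hbb-bs was 13 and 36.7 CPM at D1 and 0.453 and 0.0321 at D49. The airway secretoglobin Scgb3a2 was 29.6 and 39.5 CPM at D1 against 1.48 and 0.573 at D49, and the club cell gene Scgb1a1 was 11.1 and 24.3 CPM at D1. The epithelial adhesion gene Epcam ran the other way at 2.59 CPM in D1 control and 15.6 in D49 control. The neutrophil and monocyte gene S100a8 was 119 CPM in D1 control and 24.4 in D49 control, while its partner S100a9 was 2.58 CPM in D1 control.

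The X-inactivation transcript Xist was 346 ± 149 CPM in D1 control, 1.04 at D3, 0.682 at D7, 502 ± 139 at D21 and 1080 ± 396 at D49, and the Y-linked Ddx3y was 36.6, 220, 298, 203 and 134 CPM. The pools at D3 and D7 thus carried almost no Xist, and each of the other ages carried both transcripts. In the control steps from D1 to D3 and from D7 to D21, age therefore cannot be told apart from the sex composition of the pools. Both transcripts also differed in level between D1, D21 and D49. A difference in sex composition is thus not excluded from D1 to D49 or from D21 to D49. The sex composition of the pools is not given in the sources used here. The growth factor Igf1 was 36.7 CPM in control and 13.9 with LPS at D1, and 174 and 52.5 at D49. The iron-binding Lcn2 was 3.57 and 11.3 CPM at D1, and 0.334 and 5.64 at D49.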
